A study of Mus musculus with 9 samples.

How the data were processed

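RNA bound to 2 forms of the mRNA export protein Chtop was measured by iCLIP, in which RNA is crosslinked to protein with ultraviolet light, recovered with an antibody against the protein and sequenced. N2a cells are a mouse neuroblastoma line. Per the labels' protocols, N2a Flp-In rtTA lines carried a FLAG-tagged Chtop cDNA with or without exon 5, induced with doxycycline at 2 µg/mL for 24 hours, and cells were crosslinked at 0.15 J/cm2. Anti-FLAG immunoprecipitates of each isoform gave 3 libraries per group, from replicates that the labels call independent and handled on different days. The 3 size-matched inputs came from 2% of the lysate, run on the same kind of gel without the antibody step. These inputs came from 3 different lines: replicate 1 from the line without exon 5, replicate 2 from the line with exon 5 and replicate 3 from a FLAG-GFP line.

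The authors deposited raw counts per gene for the 5' UTR, the CDS, the 3' UTR and their sum, per the file headers. The sum equalled its parts in every cell, with 0 exceptions. Per the submitters' processing notes, the build was mm10 and TopHat2 and DESeq2 were used, with no versions. Read filtering, the counting tool and strand handling are not given in the sources used here. The reverse transcription primers held random bases, but whether reads were collapsed by them is not given in the sources used here, so intervals and floors below cover counting error only. The authors also deposited a table of 5320 genes with a normalized signal per gene part for the isoform libraries, which was the deposited count over 1 size factor per library and part for 100% of values, within 0.1%. That deposited table further holds a log2 fold change between the isoforms and an isoform class per gene part. Part lengths in bases were deposited per the file headers. In all, 9 columns of per-sample values in these tables were not used here.

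The count tables held 22442 genes, of which 11718 had a symbol in the deposited tables and 8872 were named by the length table. Coordinates are those of GRCm38.p6, the assembly of mm10. For 9 symbols, at least 2 genes carried the same name. Genes without a symbol were tested but not named.

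Library totals ran from 624062 to 1844970 counts in the immunoprecipitates and from 75504 to 173342 in the inputs, so 3 counts in a library corresponded to 2.16 to 5.67 CPM (counts scaled to a common library size with TMM) in the former and 16.8 to 21.7 CPM in the latter. The main test was the quasi-likelihood F-test of edgeR 4.0.16 (robust fit, TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15) in R 4.3.3, with all 9 libraries in 1 fit and no covariate. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values were scaled by TMM and are given as mean ± SD (n = 3 libraries per group). Parts of genes were tested in the same way, both isoforms together (6 libraries) against the 3 inputs, and isoform against isoform. Relative use of parts within a gene was tested with diffSpliceDGE of edgeR. Shares of counts per part were compared by a two-sided exact permutation test, adjusted over the 6 tests. Where every library of a group was at 0, a fold is a lower bound computed with the mean CPM of 3 counts per library of that group. With 1 to 3 counts, a ratio of summed counts over summed library sizes (scaled by TMM) is given with its exact 95% interval. This interval pools the libraries of a group, so it leaves out the spread between them.

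Before the data were examined, 24 gene lists were fixed. They were mRNA export factors, replication-dependent histones, SR proteins, hnRNPs and other splicing regulators, core spliceosome, cleavage and polyadenylation factors, arginine methylation, cytosolic ribosomal proteins, translation factors, mitochondrially encoded genes, nuclear-encoded oxidative phosphorylation, proteasome, intronless or immediate-early genes, heat shock proteins and chaperones, nuclear long non-coding RNAs, small nuclear and nucleolar RNAs, Zfp zinc finger genes, cell cycle, DNA repair, synapse and axon, neuroblastoma and sympathetic neuron genes, chromatin regulators, secretory pathway and glycoproteins, and markers of other cell types. Lists with at least 5 measured members were tested with camera of limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2). Against input, the test used the 3953 genes that the length table names. The remaining names come from a table of genes counted in the isoform libraries, so they were left out. This restriction was chosen once the tables' names were seen. The length table names only genes with a 5' UTR entry, so list tests against input may cover only part of a list. Member counts include every named gene.

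The rule for named genes was fixed at the same stage. They were Chtop, and, per comparison of gene totals, the 10 highest and the 10 lowest log2 fold changes among genes past the threshold, without overlap of the groups and with a mean of at least 10 counts. Where fewer than 5 passed, the smallest p-values filled the list to 5. Gene parts gave the 3 smallest p-values per direction (6 for relative use), and each list up to 4 members of smallest p, or 2 of highest count where none passed. Predicted genes and pseudogenes were left out.

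The pipeline was tested on simulated data with 2-, 4- and 8-fold changes. Between the isoforms, libraries were drawn from the pooled profile of the isoform libraries or of the inputs. Against input, all 9 libraries were drawn from 1 mean of these profiles. For gene totals, the threshold recovered 36.7% of 8-fold, 10% of 4-fold and 0% of 2-fold changes between the isoforms (7842 genes run), and in a fit of the 6 isoform libraries alone 60%, 29.8% and 0%. Against input it recovered 15.4% (7841 genes run) and 16.9% (7789 genes run) of 8-fold changes for the isoform with and without exon 5. The same numbers recur across groups, and the check for pairing is given in the closing section. Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters, a fold minimum of 1.5, only the groups compared, a replicate block, a correction for a length trend, leaving out each library in turn, and thinning to the shallowest library. Figures were drawn with matplotlib 3.10.9. A result for 1 gene is not reported here.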

Results

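The data comprised 9 iCLIP libraries from N2a cells: 3 of FLAG-Chtop with exon 5, 3 of FLAG-Chtop without exon 5 and 3 size-matched inputs. Totals were 783868, 851442 and 1328423 counts for the isoform with exon 5. They were 624062, 1005472 and 1844970 counts without exon 5, and 111982, 173342 and 75504 counts for the inputs. Between 9505 and 10828 genes had a count in the isoform libraries, against 4665, 7412 and 3129 in the inputs. Across genes, log CPM correlated at 0.756 to 0.823 within the isoform without exon 5, at 0.716 to 0.727 within the isoform with exon 5 and at 0.705 to 0.770 between them. The inputs correlated with each other at 0.279 to 0.377 and with the isoform libraries at 0.267 to 0.398.

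Chtop itself (ENSMUSG00000001017.15; chromosome 3, 90498539 to 90509527 in GRCm38; CDS of 831 bases and 3' UTR of 2557 bases) was counted in every immunoprecipitate. Its level was 385 ± 20.6 CPM with exon 5 and 238 ± 36.7 CPM without (SD, n = 3 each), with 247, 275 and 404 counts against 148, 187 and 291. The inputs held 76, 10 and 0 counts, the 0 being the FLAG-GFP line. The edgeR log2 fold change between the isoforms was 0.69 (SE 1.08, adjusted p = 1.00), and against input it was 1.13 (SE 1.10, adjusted p = 0.544) with exon 5 and 0.44 (SE 1.09, adjusted p = 0.835) without. Without input replicate 1, which held 76 of the input counts, these values were 3.797 (adjusted p = 0.0302, and 0.184 to 0.953 in the other settings) and 3.13 (adjusted p = 0.0518). The CDS held 58.0% ± 14.5 of Chtop counts with exon 5 and 72.8% ± 3.39 without. Counts per gene part do not separate transcripts with and without exon 5, or cDNA from the cell's own mRNA, so they do not check the isoform labels.

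The first question was which RNAs each isoform held above the background of crosslinked RNA of the same size. Among well-counted genes, Srrm2, Kmt2d, Kmt2c, Tet3, Tet2 and Map1b passed higher with both isoforms. Srrm2, a spliceosome-associated SR-related protein, reached 7808 ± 973 CPM with exon 5 against 1254 ± 194 in the inputs (log2 fold change 2.64, SE 0.28, adjusted p = 0.000228; higher in 3 of 3 libraries), and its log2 fold change was 2.76 (SE 0.28, adjusted p = 0.000133) without exon 5. The histone methyltransferase genes Kmt2d and Kmt2c rose by 3.25 and 3.78 on the log2 scale with exon 5 and by 3.35 and 3.55 without. The DNA demethylase genes Tet3 and Tet2 rose by 4.61 and 3.07, and by 4.38 and 3.69. Map1b, encoding a microtubule-associated protein of axons, rose by 1.90 (SE 0.30, adjusted p = 0.00449) with exon 5 and by 1.19 (SE 0.30, adjusted p = 0.0296) without, but its direction turned with a correction for a length trend (−0.34 and −0.97). Depleted from the immunoprecipitates were counts of Tmem38b, a cation channel gene, and Lars2, the mitochondrial leucyl-tRNA synthetase gene. In the inputs, 788 of 788 Tmem38b counts and 21342 of 21363 Lars2 counts lay in the 3' UTR. A fall of the whole mRNA is thus not shown for either gene. The CDS of Lars2 did not pass with both isoforms against input (edgeR log2 fold change 0.65, SE 1.25, adjusted p = 0.743). Tmem38b stood at 12.7 ± 13.3 CPM with exon 5 and 22.6 ± 2.30 CPM without, against 1572 ± 877 in the inputs (log2 fold change −6.89, SE 0.94, adjusted p = 0.00155, and −6.11, SE 0.91, adjusted p = 0.00312). Lars2 fell from 43313 ± 15878 to 2173 ± 208 CPM without exon 5 (log2 fold change −4.32, SE 0.29, adjusted p = 1.24e-06).

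Of 8342 genes tested, 765 passed with exon 5, 693 higher and 72 lower, and 726 passed without, 677 higher and 49 lower. For 391 and 383 of them every input was at 0. The highest bounds with exon 5 were at least 23.9-fold for Bod1l (0 counts in the inputs, 455 ± 244 CPM), 23.2-fold for the ciliary dynein gene Dync2h1, 19.5-fold for Carmil3, 17.7-fold for Zfp687 and 17.3-fold for Iqsec1 (5.18-fold without replicate 2, which held 539 of its counts). They were followed by Ptpn23 at 16.7-fold, Maskbp3 and the choline kinase gene Chka at 14.4-fold each, Usp31 at 14.2-fold and the sodium channel gene Scn3a at 13.8-fold. Without exon 5 they were at least 29.7-fold for Ptpn23 (565 ± 132 CPM), 21.8-fold for Bod1l, 17.5-fold for Unc93b1 and 17.0-fold for the importin gene Ipo13 (5.11- and 4.49-fold without replicate 1) and 16.3-fold for Rexo1. Zfp687 (16.0-fold), Carmil3 (15.6-fold), Fcho2 (14.1-fold), Usp35 (13.8-fold) and Unkl (13.4-fold) completed that set. Lower with exon 5 were Arf4, a small GTPase gene, by at least 36.7-fold (19.2-fold without input replicate 2), Rps19 by 33.2-fold (21.9-fold without input replicate 3) and the hypoxia-inducible factor gene Epas1 by 13.2-fold (2.37-fold without input replicate 1). Also lower with exon 5 were Tnfaip8 (−5.87 on the log2 scale), Rhoq (−5.72), Rpl21 (−5.68), Rpl31 (−5.57), Fau (−5.50) and Rps25 (−5.19), with SE from 1.42 to 1.68. Lower without exon 5 were the malate dehydrogenase gene Mdh2 (−5.66), Tpt1 (−5.66), Tnfaip8 (−5.62), Spock2 (−4.50), Ncbp3 (−4.03), Ttpal (−4.02), Naca (−3.82) and Rabggtb (−3.81). The groups did not overlap for 3049 genes (36.5%) with exon 5 and 3275 (39.3%) without. Chance gives 10% for libraries of 1 kind and depth. The inputs were shallower and often at 0, so the excess does not measure enrichment alone.

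These counts depended on the test, on scaling and on single libraries. The fewest genes were called with exon 5 by limma-voom (21) and without exon 5 by a fit of only the groups compared (30). The median of all genes lay at a log2 fold change of 1.03 in both comparisons under TMM and at 0.35 and 0.33 by library size alone, which called 262 higher and 128 lower with exon 5 and 210 and 86 without. Leaving out replicate 1, 2 or 3 of the isoform with exon 5 left 177, 68 and 60 genes, and leaving out those of the isoform without exon 5 left 147, 106 and 39. Without input replicate 2 the counts were 2412 and 2355, and without input replicates 1 and 3 the isoform without exon 5 had 1095 and 1107. Srrm2 passed in 17 of 19 settings in both comparisons, with log2 fold changes from 0.24 to 2.82 and from 0.42 to 2.96, Tmem38b in 19 of 19 in both, and Lars2 in 19 of 19 without exon 5, while Map1b without exon 5 passed in 6 of 19.

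**Figure D1:**
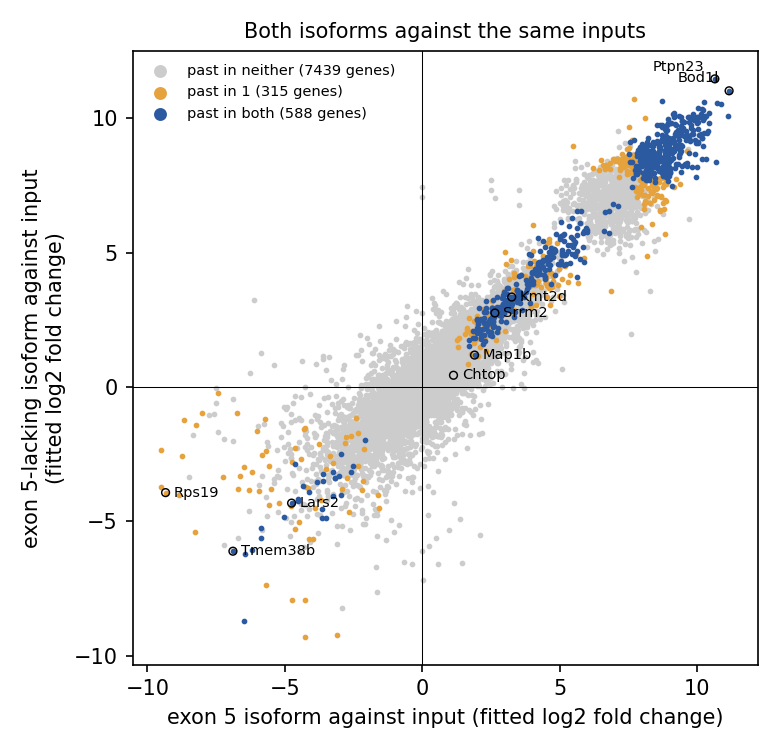
Fitted log2 fold change over input of each of 8342 genes, for the isoform with exon 5 (one axis) and without (other axis), colored by whether the gene passed in neither comparison (7439), in 1 (315) or in both (588). Genes with 0 input counts form the cloud at the upper right, where fitted values depend on the prior count and are no bounds.

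Across genes, which are not independent replicates, the 2 enrichments correlated at r = 0.940 (8342 genes), with 559 genes higher in both, 29 lower in both and 0 in opposite directions. They share their inputs: unchanged groups simulated from 1 mean profile, with simulated inputs in common, gave r = 0.768. Independent lists would share 56.2 higher and 0.423 lower genes. The covariance was 9.06 against a simulated 1.37, a difference of 7.69. The simulation used neither the real inputs nor the spread among them alone, so this difference may be too large. The 3 inputs cannot be split into sets of 2 libraries each, so part of the excess may come from the shared inputs.

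By function, mRNAs of the translation and secretory machinery lay low against input, relative to a median of 0.97 over the named genes in both comparisons. No list was placed high by camera among the genes that the length table names, whereas over all named genes chromatin regulators were placed high in both comparisons and Zfp genes with exon 5. With an estimated correlation, tested on the former genes, neither passed (adjusted p = 0.799 for both with exon 5, and 0.793 and 0.956 without). Of 34 measured ribosomal protein genes, 0 rose in either comparison and 5 fell with exon 5 (7 adjusted over the list alone), among them Rps19, Rpl31, Fau and Rpl21. Without exon 5, 1 fell (0 adjusted over the list alone), Rpl36, by at least 12.5-fold. The median of the 33 tested members was −2.96 and −2.61 (camera adjusted p = 8.76e-20 and 1.91e-21; adjusted p = 0.0965 and 0.0793 with an estimated correlation). Of 19 secretory and glycoprotein genes, 2 fell in each comparison (4 and 2 adjusted over the list alone): the oligosaccharyltransferase gene Ddost (−4.63) and the lysosomal Lamp1 (−2.52) with exon 5, and Lamp1 (−2.94) and the integrin gene Itgb1 (−2.31) without. The low-density lipoprotein receptor family gene Lrp1 instead rose without exon 5 (2.64). The median of the 14 tested was −1.85 and −1.53 (adjusted p = 1.26e-06 and 2.22e-06; adjusted p = 0.219 and 0.270 with an estimated correlation). Among 20 heat shock and chaperone genes 0 passed in either direction, with values of −1.25 and −1.05 for Hsp90b1 and −1.90 and −0.79 for Hspa5. The median of the 11 tested was −1.09 and −1.05 (adjusted p = 7.02e-06 and 1.83e-05; adjusted p = 0.149 and 0.176 with an estimated correlation). Of 22 translation factor genes, Eif1 fell with exon 5 (−3.75) and 0 passed without. Over the 14 tested, the median was −0.23 and −0.58 (adjusted p = 0.0318 and 0.0160; adjusted p = 0.295 and 0.270 with an estimated correlation). That call was lost with exon 5 without its replicate 2 (adjusted p = 0.0659) and without input replicates 1 and 2 (0.0691 and 0.101), and without exon 5 without the same inputs (0.0580 and 0.0700). Without exon 5, camera also placed 8 neuroblastoma genes low (median −0.27, adjusted p = 0.00513; adjusted p = 0.338 with an estimated correlation and 0.0568 without input replicate 2), although Alk, outside these 8, rose by 3.83. It also placed 17 hnRNP genes low, with a positive median of 0.11, a mean of −0.14 and a median of −0.70 by library size alone (adjusted p = 0.0481; adjusted p = 0.793 with an estimated correlation). The hnRNP call was lost over all named genes (adjusted p = 0.0602), without each replicate lacking exon 5 (0.0693, 0.109 and 0.0587) and without input replicates 1 and 2 (0.345 and 0.198).

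**Figure D2:**
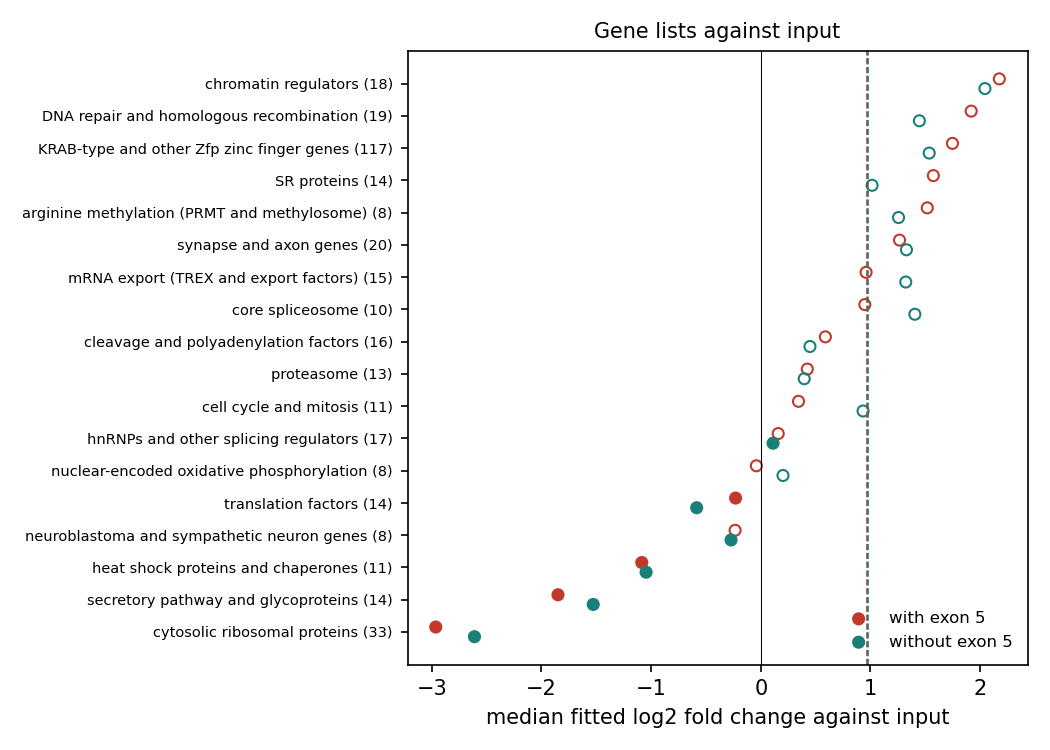
Median log2 fold change over input of each gene list, per isoform, with filled points for lists that camera placed apart from the remaining named genes and the dashed line at the median of named genes (0.97). Ribosomal protein genes lay lowest, at −2.96 and −2.61, and medians include fitted values of genes with 0 input counts.

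Of lists that camera did not place apart among the genes named by the length table, 13 of 48 chromatin regulators rose in each comparison and 0 fell (21 and 22 adjusted over the list alone). The median of the 18 tested was 2.18 and 2.04 (1.95 and 2.04 with genes at 0 set to their bound; adjusted p = 0.0676 and 0.0557; adjusted p = 0.799 and 0.793 with an estimated correlation). Over all 48, camera placed them high (adjusted p = 0.0107 and 0.0105). Fits without a library filtered their genes anew, so the members tested could differ from these 18. In such fits camera also placed the list high with exon 5 without input replicates 2 and 3 (adjusted p = 0.0176 and 0.0444). Without exon 5 it was so without replicates 1, 2 and 3 of that isoform (adjusted p = 0.0471, 0.0371 and 0.0339) and without input replicates 2 and 3 (0.0110 and 0.0321). Of 32 DNA repair genes, 5 and 4 rose (8 in each adjusted over the list alone). The mismatch repair gene Msh6 was at least 7.23- and 7.80-fold higher and the nuclease scaffold gene Slx4 at least 9.70- and 7.11-fold. Fancm, a helicase gene of the Fanconi anemia pathway with 1 input count, had ratios of 107 (19.2 to 4241) and 92.8 (16.6 to 3674). Over the 19 tested, the median was 1.92 and 1.45 (1.55 and 1.08 at the bound; adjusted p = 0.0778 and 0.222). Among all 6785 named genes tested, 683 rose with exon 5 and 672 without, and 35 and 21 fell. Of 202 Zfp zinc finger genes, 19 and 16 rose, no higher a share than among all named genes, and 0 fell. Adjusted over the list alone, 29 and 22 rose. Ratios were 206 (36.9 to 8135) and 191 (34.2 to 7547) for Zfp280b and 139 (24.9 to 5515) and 112 (20.1 to 4444) for Zfp236, each with 1 input count. The median of the 117 tested was 1.75 and 1.54 (1.08 and 0.96 at the bound; adjusted p = 0.0612 and 0.272; adjusted p = 0.799 and 0.956 with an estimated correlation). With exon 5 they were placed high over all named genes (adjusted p = 0.0434), without its replicates 1 and 3 (0.0458 and 0.0391) and without input replicate 3 (0.0444). Of 24 mRNA export genes, 6 rose in each comparison (Zc3h11a under 2 identifiers) and 1 fell, with Thoc1 of the THO complex at least 4.78- and 4.47-fold higher and Poldip3 at least 6.20-fold higher with exon 5 (median of the 15 tested 0.96 and 1.32; adjusted p = 0.708 and 0.604). Ncbp3, which fell without exon 5, belongs to that list.

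Among the same genes, camera placed none of the following lists apart, except the hnRNP and neuroblastoma genes without exon 5 given above. Counts and medians in this paragraph cover all named members. Medians have genes at 0 set to their bound, except those by library size alone, which use fitted values, so the 2 differ in both choices. Of 25 SR protein genes 3 and 4 rose, Son among them (2.20, SE 0.48, and 1.62, SE 0.47; −0.34 and −0.87 with a correction for a length trend, and past the threshold in 10 and 4 of 19 settings), with medians of 0.92 and 0.96. Of 35 hnRNP genes, 2 rose and 1 fell with exon 5 and 1 rose without: Ewsr1 rose (2.52 and 2.91) and Hnrnpr fell with exon 5 (−2.76), with medians of 0.58 and 0.48 but −0.20 and −0.32 by library size alone. Of 21 spliceosome genes 2 and 3 rose, among them Eftud2 (2.70 and 3.36), with medians of 1.04 and 1.39. Of 35 synapse and axon genes 6 and 4 rose, including Map1b and, with exon 5, the ankyrin gene Ank3 (2.30), and without exon 5 the neuroligin gene Nlgn2 (4.96, SE 1.17), with medians of 1.48 and 1.34. Of 26 cell cycle genes 1 rose in each comparison, the kinetochore gene Cenpf (2.84 and 2.77), with medians of 0.42 and 0.86, the former −0.28 by library size alone. Of 22 cleavage and polyadenylation genes 1 rose in each (medians 0.73 and 0.57, the latter −0.17 by library size alone). Of 14 proteasome genes 1 rose in each (0.40 and 0.33, but −0.65 and −0.55 by library size alone), and of 10 arginine methylation genes 0 passed (0.71 and 0.39). Of 12 oxidative phosphorylation genes 1 fell with exon 5 (medians 0.08 and 0.67, the former −0.19 by library size alone). Of 16 neuroblastoma genes 1 rose and 1 fell with exon 5 and 1 rose without (0.28 and 0.17, but −0.50 and −0.58 by library size alone).

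Some of these lists were placed low by camera in other settings. Each fit without a library filtered its genes anew, so the members tested could differ from those of the main fit. The oxidative phosphorylation list had 8 tested genes in the main fit (camera adjusted p = 0.0523 and 0.0845, and 0.219 and 0.270 with an estimated correlation). With exon 5 it was placed low without replicates 1, 2 and 3 of that isoform (0.0144, 0.00892 and 0.000615) and without input replicates 1 and 3 (0.0304 and 0.0202). For all 12 it was so over all named genes (0.0434). Without exon 5 the list was placed low without each replicate of that isoform (0.0275, 0.00753 and 0.00206) and without input replicates 1 and 3 (0.0414 and 0.0199). With exon 5, the neuroblastoma list (adjusted p = 0.0523; adjusted p = 0.671 with an estimated correlation) was placed low by library size alone (0.0284), over all named genes (0.0107) and without input replicate 1 (0.0493). The hnRNP list with exon 5 (adjusted p = 0.0778; adjusted p = 0.799 with an estimated correlation) was placed low by library size alone (0.0247), over all named genes (0.0494) and without input replicate 3 (0.0222). Lists with too few members for the test were intronless or immediate-early genes (4 and 3 of 13 rose), histones (0 of 11 passed), long non-coding RNAs (0 of 1) and markers of other cell types (0 of 1, Mbp). Mitochondrially encoded genes and small nuclear RNAs had 0 named members.

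The next question was where on the mRNA the isoforms were held. Counts shifted from the 3' UTR to the CDS in the immunoprecipitates. The CDS held 67.4% ± 1.07 of counts in the 6 isoform libraries and 46.7% ± 1.13 in the 3 inputs, a difference of 20.8 points (exact permutation p = 0.0119, the smallest that 84 splits can give, adjusted p = 0.0357). The 3' UTR held 29.2% ± 1.36 and 50.2% ± 1.31, a difference of −21.0 points with the same p. Leaving out any 1 library left too few splits for an adjusted p under the threshold (0.0536 without an isoform library, 0.107 without an input), with CDS differences of 20.2 to 21.3 points. The 5' UTR held 3.35% ± 0.330 and 3.11% ± 0.275 (exact permutation p = 0.286, adjusted p = 0.571), a difference not larger than the spread.

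**Figure D3:**
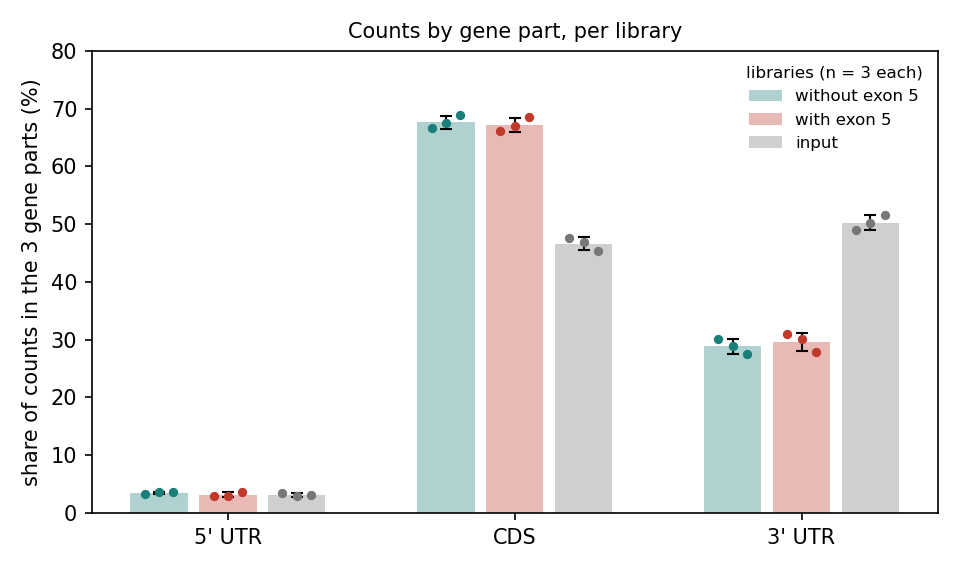
Percent of each library's counts in the 5' UTR, the CDS and the 3' UTR, with bars for group means, error bars for the SD and points for the libraries (n = 3 per group). The CDS share was 67.4% over the 6 isoform libraries and 46.7% over the inputs.

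By part, 331 of 661 genes passed in the 5' UTR (323 higher, 8 lower), 1564 of 6376 in the CDS (1480 higher, 84 lower) and 1104 of 4984 in the 3' UTR (1031 higher, 73 lower) with both isoforms against input. Thinned to the shallowest library, which leaves fewer counts and evens out depth, 12, 292 and 128 genes passed. Each input held 2282 to 5008 counts in 5' UTRs, against 20608 to 67110 in the isoform libraries. The mannosidase gene Man2a1, the phosphatase gene Dusp4 and the neuronal transcription factor gene Myt1l were at least 18.0-, 15.9- and 11.4-fold higher in the 5' UTR. In the CDS, Arhgef11 and the O-GlcNAc transferase gene Ogt were at least 33.6- and 27.6-fold higher, and Srrm2 rose by 2.65 (SE 0.32, adjusted p = 0.000506). In the 3' UTR, Avl9 rose by 3.91 (SE 0.45, adjusted p = 0.000120) and Fbxl20 by 3.48 (SE 0.50), and the alpha-actinin gene Actn1, with 1 input count, had a ratio of 320 (57.4 to 12644). Lower were Rps25 (−6.35, SE 1.34), Akt2 (−4.07, SE 1.23) and Eif4g1 (−3.78, SE 1.14) in the 5' UTR. In the CDS they were the basigin gene Bsg (−3.92, SE 0.72), Tnfaip8 (−5.33, SE 0.99) and Emb (−4.00, SE 0.80). In the 3' UTR they were Lars2 (−3.88, SE 0.32, adjusted p = 9.62e-07), Tmem38b (−5.78, SE 0.81) and Nopchap1 (−2.82, SE 0.41). Eif4g1 turned to 0.61 without input replicate 1, and the counts of genes moved to 176 and 203 (5' UTR, without input replicates 1 and 3), 2715 (CDS) and 1817 (3' UTR, both without input replicate 2).

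Within genes, 452 of 4163 changed their use of parts, with the CDS relatively higher in 342 and lower in 109 and the 3' UTR relatively lower in 331 and higher in 112. The clearest were the ubiquitin ligase gene Shprh (3' UTR −3.38, adjusted p = 0.000625), Ogt (−2.84), Lpp (−3.14), Zfp871 (−1.19), Nopchap1 (−0.20) and the heterochromatin protein gene Cbx5 (−0.62, adjusted p = 0.00118). In Shprh, Ogt, Zfp871, Nopchap1 and Cbx5 the inputs had 0 CDS counts while the 3' UTR was counted in at least 2 of the 3. With only parts of at least 10 counts on average in both groups 12 genes passed and with a replicate block 68. Leaving out replicate 2 or 3 without exon 5, or replicate 3 with exon 5, left 243, 270 and 299.

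The last question was whether exon 5 changed which RNAs were held. No gene passed between the isoforms in the main edgeR fit of all 9 libraries: 0 of 8342 genes, with 93 at an unadjusted p under 0.05, and 0 with DESeq2, with 220. Limma-voom and an edgeR fit of the 6 isoform libraries alone each called 2, and edgeR with no filter called 4. The common dispersion was 0.884 in the main fit and 0.388 in the fit of 6 libraries, so the fit with the inputs assumed a wider spread. In the fit of 6 libraries, 625 of 7931 genes (7.88%) had an unadjusted p under 0.05, and 331 of 2490 genes (13.3%) with a mean of at least 100 counts. The count of 0 therefore does not show that exon 5 makes no difference. The groups did not overlap for 1161 genes (13.9%, where chance gives 10%). Map1b stood at 11281 ± 2437 CPM with exon 5 and 6912 ± 778 without (log2 fold change 0.71, SE 0.30, adjusted p = 1.00; no overlap). The smallest p-values belonged to genes counted in 1 isoform almost alone, none past the threshold. Fstl4 had 300 counts with exon 5 and 1 without (ratio 343, 61.1 to 13596), and the kinase gene Lrrk1 had 85 and 2 (ratio 48.6, 13.0 to 408). Rpl24 had 59 and 0 (at least 7.56-fold, 3.08-fold without replicate 2), Afmid 297, of which 272 in 1 library, and 15 (log2 fold change 4.40, SE 1.64) and Spock2 127 and 15 (2.93, SE 1.10). In the other direction Arf4 had 0 counts with exon 5 and 81 without (at least 7.25-fold lower), Eif1ad 0 and 105 (8.90-fold), Epas1 0 and 76 (6.65-fold) and Sar1b 0 and 62 (5.67-fold), and Rhoq had 4 and 133 (−4.54, SE 1.39). The adjusted p was 1.00 for each.

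Gene parts also gave counts of 0 between the isoforms. In simulated data, the tests recovered 18.3%, 35.6% and 13.8% of 8-fold changes in the 5' UTR, the CDS and the 3' UTR and 0% for the use of parts, so a count of 0 for use says little. In the 5' UTR 0 of 661 genes passed (12 at an unadjusted p under 0.05; DESeq2 0 and 20), in the CDS 0 of 6376 (82; DESeq2 0 and 167), in the 3' UTR 0 of 4984 (93; DESeq2 0 and 164) and in the use of parts 0 of 4163 (71; Simes test 0 and 39). Rack1, encoding a ribosome-bound scaffold protein, had 1 count in its 5' UTR with exon 5 and 93 without (ratio 0.0126, 0.000317 to 0.0722). Its CDS changed by 0.38 in relative use. Paqr3 had 0 and 157 CDS counts (at least 13.0-fold lower with exon 5), Mapk8 175 and 8 CDS counts (4.24, SE 1.55), Armc8 0 and 81 counts in the 3' UTR (at least 8.18-fold lower) and Taok3 479 and 42 (3.33, SE 1.28). The shares were 67.2% ± 1.22 and 67.7% ± 1.11 for the CDS (exact permutation p = 0.6), 29.6% ± 1.60 and 28.8% ± 1.26 for the 3' UTR (exact permutation p = 0.5) and 3.19% ± 0.396 and 3.52% ± 0.186 for the 5' UTR (exact permutation p = 0.4; adjusted p = 0.6 for all), where 3 libraries against 3 cannot give a p below 0.1.

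Of 20 gene lists tested between the isoforms, 0 were placed apart by camera and 0 of their members passed, with 1 list at an unadjusted p under 0.05. That list was the Zfp zinc finger genes, of which 131 of 202 were positive (median 0.25, adjusted p = 0.0797; adjusted p = 0.995 with an estimated correlation). Without replicate 1 of the isoform without exon 5, and in the 6 isoform libraries alone, its adjusted p was 0.0434 and 0.0323, and over the remaining settings it ranged from 0.0573 to 0.995. The neuroblastoma genes were next (16 genes, 11 positive, median 0.33, adjusted p = 0.508), and the other 18 lists had medians from −0.28 (cell cycle) to 0.30 (cleavage and polyadenylation), with an adjusted p of at least 0.652. In the authors' deposited table, which gives log2 fold changes of the isoform with exon 5 over the other for gene parts, 336 genes were classed to the isoform with exon 5 and 377 to the other in the CDS, 275 and 282 in the 3' UTR and 37 and 62 in the 5' UTR. Its values for Map1b were 0.78 in the CDS and 0.61 in the 3' UTR, and for Chtop 0.40 and 1.34.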

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

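Of 21 results examined for a library far from the rest of its group, 4 had a gap, as a share of the range of the 6 isoform libraries, above Dixon's 95% critical value, which chance passes in about 1 of 20 results. CPM in this paragraph are scaled to the counts of that gene part alone, so few 5' UTR counts give a high CPM. The 5' UTR of Rps25 had a gap of 1: replicate 2 without exon 5 stood at 206 CPM (4 counts) and the other isoform libraries at 0, which fixes a gap of 1. The 5' UTR of Akt2 had 0.754, with replicate 3 with exon 5 at 626 CPM (18 counts) and the others at 0 to 154. For the CDS of Bsg the gap was 0.821, with replicate 2 without exon 5 at 146 CPM and the others at 30.8 to 51.4. For the 3' UTR of Fbxl20 it was 0.642, with replicate 3 without exon 5 at 24649 CPM and the others at 9126 to 14678. The cause was not tested.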

How the results depend on the processing

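Tests on thinned counts, the other choice of named genes and the tables' own numbering of inputs were added after the results were seen. Paired differences of shares and bounds without single libraries were added later still. The cause of changes between settings was not tested. Thinning leaves fewer counts and also evens out the depth of inputs and isoform libraries, and these effects were not separated. The CDS and 5' UTR counts and the parts in use between isoforms were 0 in the settings run, which for the use of parts says nothing on stability (0% of simulated 8-fold changes recovered). The CDS and 3' UTR shares against input kept their direction, but with any library left out the adjusted p was 0.0536 to 0.107, the smallest these splits allow.

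Between isoforms, gene totals called 0 genes, 4 with no filter, 2 with limma-voom and 2 with only the groups compared; 3' UTRs called 0, and 2 with no filter. Lists called 0, 1 with only the groups compared, and 0 to 1 leaving out a library.

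With exon 5 against input (765 genes): DESeq2 1708, library size 390, upper quartile 437, no filter 1211, limma-voom 21, only the groups compared 29, length trend 507, thinned 279, leaving out a library 60 to 2412. Without exon 5 (726): DESeq2 1654, library size 296, upper quartile 358, no filter 1184, limma-voom 42, only the groups compared 30, length trend 429, thinned 268, leaving out a library 39 to 2355.

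Deviations of same-numbered isoform libraries from their group means correlated at r = −0.001, 0.031 and 0.039, and replicate 1 without exon 5 correlated best with replicate 2 of the other isoform (0.017). Over genes of mean 50 counts the values were 0.032, 0.038 and 0.103, each the highest for its library without exon 5. The numbers were not taken to pair the libraries, since not every correlation was over 0.1, but a weak pairing is not excluded; the labels do not say whether same-numbered libraries share a day. Within same-numbered libraries the CDS share with exon 5 lay −0.529, −0.510 and −0.311 points from that without, and the 3' UTR share 0.869, 1.16 and 0.303 points (exact permutation of signs, p = 0.25 each, the smallest that 3 pairs can give). A replicate block gave 273 with exon 5 and 284 without, 296 and 294 with the tables' numbering, 197 and 172 with the length trend, and 68 genes for use of parts. It ended the hnRNP list call without exon 5, gave rho = 0.0445 for length without exon 5, and changed no other call of a count or list.

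Both isoforms against input: 5' UTR 331 genes, 192 with no filter, 12 thinned, 176 to 346 leaving out a library; CDS 1564, 292 thinned, 1156 to 2715; 3' UTR 1104, 675 with factors of gene totals, 1690 with DESeq2, 128 thinned, 744 to 1817; use of parts 452, 12 with parts of at least 10 counts, 22 by Simes, 63 thinned, 243 to 589. The 5' UTR share differed by 4.20 points as a median over genes (exact permutation p = 0.0119), where the median of every input was 0, a floor at their depth that fixes this p.

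Lists with exon 5 (4): 0 with an estimated correlation, 10 with fry (which tests against no change, 9 of them higher), 9 with all named genes (chromatin regulators and Zfp genes higher, 7 lower), 4 to 8 leaving out a library, of which not all are the same lists. Without exon 5 (6): 0 with an estimated correlation, 7 with fry, all higher and without the ribosomal list (adjusted p = 0.0518), 4 to 8. The enrichments correlated at 0.940, 0.964 for genes of mean 50 counts, 0.931 to 0.954 leaving out a library. Length rho between isoforms was 0.0945, 0.141 at mean 50 counts, 0.0601 to 0.110; with exon 5 0.112, 0.0300 to 0.124; without 0.0829, 0.00790 to 0.0908. The CDS share between isoforms was −0.450 points and −1.11 to 0.145 leaving out a library, with 0.145 without replicate 3 lacking exon 5 and 0.0883 without replicate 1 with exon 5.

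Directions turned for Son with exon 5 (−0.34 by length trend, −0.046 with the block added) and without (−0.87, −0.58), Map1b with exon 5 (−0.34, −0.30) and without (−0.97, −0.91) and Chtop with exon 5 (−0.86 by length trend; 0.57 to 3.797 leaving out a library). Chtop without exon 5 turned with DESeq2 (−0.10), library size (−0.39), upper quartile (−0.25), block and length (−0.52), length trend (−1.62), thinning (−0.59) and without input replicate 3 (−0.12, the range leaving out a library being −0.12 to 3.13). Eif4g1 in the 5' UTR turned without input replicate 1 (0.61, range −4.15 to 0.61). Of 837 values of the 45 named genes with exon 5, 607 kept direction and side of the threshold, and of 843 without exon 5, 599; between isoforms 193 of 193 did. Depth limits all of these: 3 counts per input stand at 16.8 to 21.7 CPM, and folds against inputs at 0 are bounds only.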

Other observations

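The genes in this paragraph were chosen after their values were seen. In a fit of the 6 isoform libraries alone, Cnr1, the cannabinoid receptor gene, stood at 649 ± 92.7 CPM with exon 5 and 150 ± 51.6 without (log2 fold change 2.10, SE 0.30, adjusted p = 0.0215 with edgeR's quasi-likelihood test, 0.0215 to 1.00 over 10 settings; no overlap). It was 1 of 2 genes past the threshold among 7931, with 625 at an unadjusted p under 0.05. The other, lower with exon 5, has no symbol. In input replicates 1, 2 and 3 Cnr1 had 0, 120 and 0 counts, the 120 from the line with exon 5. The gene without a symbol had 53, 0 and 0, the 53 from the line without exon 5. Each line had 1 input, so for these genes RNA level in the lines and binding cannot be told apart. In the authors' deposited table the log2 fold change of Cnr1 was 1.77 in the CDS and 2.31 in the 3' UTR. Limma-voom called the ubiquitin ligase gene Huwe1 higher (0.81, adjusted p = 6.92e-05 to 1.00 over 11 settings) and the centromere chaperone gene Hjurp lower with exon 5 (−0.89, adjusted p = 0.00395 to 1.00 over 11 settings). The 4 genes called with no filter were Rpl22l1 (706 counts in 1 library) and 1700028K03Rik (266 counts in 1 library), both higher, and 2 lower genes without a symbol. Of further genes counted 100 times or more on average and without overlap, those of smallest p did not pass (adjusted p from 0.182 to 0.343). Higher with exon 5 were Cstf2 (2.40), Lrrn3 (2.09), Syt6 (1.66), Tspyl2 (1.65), Ank3 (0.97), the sodium channel gene Scn2a (1.43), Map1b (0.71), Ggt7 (1.01), Klf7 (1.17), Tln2 (1.81), Cux1 (1.51), the netrin receptor gene Unc5c (1.57) and the synaptic scaffold gene Dlg2 (1.43). Lower were Tmbim6 (−2.58), Neo1 (−1.16), the circadian gene Per1 (−1.70), Tiam2 (−2.01), Slc3a2 (−0.92), Hbs1l (−1.60), Rtn4 (−1.28), Dock4 (−0.90), Arpc2 (−2.16), Hdlbp (−1.20), Mnt (−1.40), Urb2 (−0.87) and the histone transcription factor gene Npat (−1.03). The synapse list had an adjusted p of 0.642 in the same fit.

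Genes with a longer CDS stood higher over input: rho = 0.313 with exon 5 and 0.301 without. For 3' UTR length rho was −0.0814 and −0.112, and for total length 0.112 and 0.0829. Genes that passed higher had a median CDS of 2835 and 2806 bases, those lower 886.5 and 1035, and all tested genes 1698.5. Lars2 held 5.22% to 6.19% of input counts and 0.124% to 0.187% of isoform counts, nearly all in its 3' UTR (21342 counts in the inputs), while its CDS had a log2 fold change of 0.65 (SE 1.25, adjusted p = 0.743).

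Both tests of the CDS pattern and the scaling test of the ribosomal genes were chosen after the results were seen, and the length test and the splits before. A candidate explanation of the shift to the CDS is that a few genes take most counts. The difference of 20.8 points was 18.1 without the 20 genes of highest count, which counts against that as the whole cause. A second is that other genes were counted in the inputs. Within 318 genes the median share differed by 11.8 points, which counts against that as the whole cause. The antibody step and binding by Chtop stay confounded, and this was not tested.

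The low position of ribosomal protein genes may come from scaling or from short mRNAs. Over 5 scalings and both isoforms the list median lay at least 2.61 below the median of named genes, the smallest distance being with the length trend. A scaling of whole libraries moves both medians nearly alike, so their distance is no test of scaling. Of 10000 lists matched by length and mean count, 0% had a median as low, and the members' median length was 914 bases against 1112 in the matched genes. Reads shared with pseudogenes could also lower the counts, but in inputs and immunoprecipitates alike. Whether they changed the position against input was not tested.

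Other splits of the libraries into groups of the same sizes were tested for the same counts. With exon 5 against input the real count of 765 was reached in 1 of 10 splits (highest other 0), without exon 5 726 in 1 of 10 (highest other 0), and list calls of 4 and 6 in 1 of 10 each (highest other 3). Between the isoforms the counts of 0 for totals, parts, use and lists were reached in 10 of 10 splits, which any count of 0 must be, so nothing follows from that. The 1161 genes without overlap were reached in 1 of 10 (highest other 983). These 10 splits are too few for a share under 0.05. Against input, 84 splits reached the real counts once each: 331 in the 5' UTR (highest other 0), 1564 in the CDS (2), 1104 in the 3' UTR (2) and 452 for use of parts (1). That is 1 of 84 splits, the smallest share they can give, which makes a random grouping an unlikely source of these counts. Every other split mixed inputs with isoform libraries, so the splits show only that these 2 kinds of library differ.

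In the authors' deposited table, genes were classed by a log2 fold change of 1 in the same direction in all replicates. Applied to ratios of its mean signals in place of its log2 fold changes, that rule gave 711 genes in the CDS, 554 in the 3' UTR and 100 in the 5' UTR, and 337 to 380, 218 to 308 and 41 to 57 with the isoform labels of 1 same-numbered pair swapped (4 settings of the labels).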
